A study of Mus musculus with 2 samples.

How the data were processed

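The series holds H3K4me1 ChIP-seq of mouse forebrain at embryonic day 13.5, with 2 biological replicates of 1 group per the labels, each pooled from male and female embryos. Both samples were used, grouped by the labels, and there was no second group to compare.

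The deposited files were 4 peak lists on mm10 in narrowPeak form, per the deposited file descriptions. There was 1 list for each replicate, 1 pooled list made from the filtered alignments of both, and 1 replicated list made from the pooled list and both replicates' lists. The list of replicate 1 was made from 1 more input file than that of replicate 2, and the deposited descriptions do not say what kind of file it was, so the controls used may differ between replicates. The peak caller, its version, its threshold and the aligner are not given in the sources used here. Each peak's fold enrichment, a ratio over control or background, is the authors' own value. The deposited −log10 p and −log10 q values were also the authors' and were used only to filter or rank peaks within a list. The deposited score, a rescaled −log10 p, and the deposited summit offset, in bp from the peak start, were not used. The lists give no read counts, so depth is unknown and no interval that needs depth is given. The lowest −log10 p was close to 2 in each list, and 85.4% of replicate 1 peaks and 87.3% of replicate 2 peaks had a −log10 q of at least 2. A calling threshold of this kind leaves out weak regions, so a gene at 0% had no listed peak, which is not a measurement of no H3K4me1.

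Peaks on the 19 autosomes and the X chromosome were analysed. Gene models were the protein-coding genes of GENCODE release M21, with 1 TSS per gene, and sequence came from the matching GRCm38 assembly. Observed to expected CpG in the 500 bp on either side of a TSS set the classes CpG-rich (at least 0.6) and CpG-poor (below 0.4). Coverage was the percent of the 50 kb on either side of the TSS overlapped by peaks. A window can also hold TSSs of other genes, so its coverage may not be that of the named gene alone. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, samtools 1.23.1 and matplotlib 3.10.9.

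Gene lists, tests and the rule for named genes were fixed before the data were examined. The 24 lists covered telencephalic patterning transcription factors, cortical excitatory, ganglionic eminence and GABAergic, radial glia, pan-neuronal, diencephalon, midbrain and hindbrain, Hox, morphogen and signalling, oligodendrocyte, astrocyte, choroid plexus, endothelial, microglia, meninges, erythroid, cardiac, hepatic, skeletal muscle, epidermal and housekeeping genes, non-neural and forebrain transcription factors, and olfactory and vomeronasal receptors. Of 1880 list entries 1, Sry, was not found on the chromosomes used. Each list's median was set among 10000 random lists of the same size, drawn within 30 strata of TSS number and gene length of which the smallest held 50 genes, and p-values were adjusted over the lists by Benjamini-Hochberg at a threshold of 0.05. The transcription factor contrast used a two-sided permutation test of 100000 resamples. Backgrounds for overlap and genomic position came from 100 circular shifts within chromosomes. Values per replicate come from that replicate's own list and are given as mean and SD.

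The genes named are, from each list, the 3 with the highest and the 1 with the lowest coverage, the 10 genes with the highest coverage overall among genes whose windows do not overlap, the 5 peaks of highest fold enrichment, and the regions between Dlx1 and Dlx2 and between Dlx5 and Dlx6. Other genes are said to be chosen after their values were seen. List members whose windows overlap share peaks, and 35 of the 35 forebrain transcription factors, 26 of the 33 non-neural ones and 12 of the 18 patterning factors are also in another list.

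The list test was tested on simulated lists of 20 genes over 21728 genes, after coverage was permuted among genes of the same stratum. The permutation removes the sharing of peaks between overlapping windows, so lists with such windows, as the Hox list, were not checked. It called 6.5% of 200 unchanged lists at an unadjusted threshold, and 34%, 70%, 92% and 94% of lists with coverage raised 1.5, 2, 3 and 4 times. The transcription factor test, on lists drawn from the same genes, called 4.5% of unchanged pairs and 73% of those raised 2 times.

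Alternatives covered other overlap rules, a −log10 q of at least 2, the stronger 50% of peaks, equal numbers of peaks, merging within 1 kb, the pooled list, each replicate left out, other promoter distances, TSSs of every transcript, windows of 10 and 100 kb, peak number in place of coverage and random lists without matching. Random lists matched also on GC content (each stratum divided into 5), on GC content in place of gene length, or on mean coverage, 1 gene per run of overlapping windows, autosomal genes alone and a log2 ratio with a pseudocount of 1% were chosen after seeing the data.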

Results

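Monomethylation of lysine 4 of histone H3 (H3K4me1), a mark known from enhancers and from the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing in the forebrain of mouse embryos aged 13.5 days. The forebrain at this age holds the developing cortex, the ganglionic eminences and the diencephalon. The series held 2 biological replicates of 1 group, each from male and female embryos together, and no other tissue, age or mark. Replicate 1 had 185642 peaks that covered 100.3 Mb, and replicate 2 had 191079 peaks that covered 115.7 Mb. The authors' pooled list held 211084 peaks, and their replicated list 128488 peaks over 124.0 Mb, which is 4.71% of the full length of the chromosomes used, unknown bases included. The peak lists give no read counts, so the sequencing depth behind each value was unknown. Values are from the replicated list unless a replicate is named, and positions are on mm10.

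The first question was around which genes of the forebrain and of other tissues the mark lay. Genes of the forebrain, of neural progenitors and of forebrain signalling had more of the surrounding sequence covered by H3K4me1 peaks than matched random genes. Over the 20 radial glia and neural progenitor genes, a median of 19.9% of the 50 kb on either side of the transcription start site (TSS) was covered, 6.37 times the 3.12% of random lists. The 21 morphogen and signalling genes of the forebrain had a median of 17.2% (4.24 times), and the 18 telencephalic and forebrain patterning transcription factors 17.0% (5.98 times). These ratios depend on the matching. With GC content added to it they were 2.72, 1.995 and 4.27, with GC content in place of gene length 2.63, 1.91 and 3.395, and without matching 3.70, 3.20 and 3.18. Both settings with GC content were chosen after the data were seen. Hox cluster genes, which pattern the trunk and hindbrain, had 5.06%. The 1464 olfactory and vomeronasal receptor genes had a median of 0%.

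Among the patterning transcription factors, Emx1, a regulator of the dorsal telencephalon (chromosome 6, 85187438 to 85204462), had 38.5% of its window covered, with 31.5% ± 1.404 (SD, n = 2) over the replicates' own lists. Pax6, needed for cortical progenitors and eye development (chromosome 2, 105668900 to 105697364), had 32.1%, and its replicates 27.0% ± 2.81 (SD, n = 2). Lhx2, a selector of cortical identity, had 29.7%, and Hesx1 was the lowest member at 5.85%. All 18 members lay above the median of their matching stratum. Such medians can be low, since Nkx2-1, at 2.73% of its window, was at percentile 64.6 of its stratum. All 10 astrocyte genes also lay above theirs, though that list did not pass, so this count alone does not set a list apart. The adjusted p was 0.000686 (n = 18 genes). The list median of the replicates was 14.6% ± 2.32 (SD, n = 2).

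The 20 genes of the cortical excitatory lineage had a median of 14.9% against 3.50% in random lists (n = 20 genes, adjusted p = 0.000686), and all 20 lay above the median of their stratum. Bcl11b, a transcription factor of deep-layer projection neurons (chromosome 12, 107910403 to 108003602), had 50.8% covered by 13 peaks. Neurod2 (chromosome 11, 98325415 to 98329648) had 45.0% and Nfia 35.9%, while the glutamate transporter gene Slc17a6 had 4.64%. The 20 genes of the ganglionic eminence and GABAergic lineage had a median of 12.8% against 3.53% (n = 20 genes, adjusted p = 0.000686). Zeb2 (36.9%), Meis2 (32.6%) and the vesicular GABA transporter gene Slc32a1 (27.2%) were highest there, and Nkx2-1, a regulator of the medial eminence, lowest at 2.73%. Over the replicates the medians of these lists were 13.3% ± 1.32 and 11.2% ± 2.39 (SD, n = 2).

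Among progenitor genes, the receptor gene Notch1 (chromosome 2, 26457903 to 26516663) had 45.4%, the intermediate filament gene Nes 36.9% and Sox1 36.2%. The windows of Nes and of Neurod2 above also hold TSSs of other genes. The X-linked Sox3 was lowest at 3.43%. The replicates' list medians averaged 18.5% ± 1.13 (SD, n = 2). All 20 members lay above the median of their stratum (n = 20 genes, adjusted p = 0.000686). Among signalling genes, Fgfr3 had 33.3%, the Hedgehog receptor gene Ptch1 32.3%, the Wnt target gene Axin2 31.3% and Spry2 6.65% (list of n = 21 genes, adjusted p = 0.000686). Their list median over the replicates was 15.0% ± 1.76 (SD, n = 2). The 35 forebrain transcription factors had a median of 16.3% against 2.71% (n = 35 genes, adjusted p = 0.000686). Over the replicates it was 14.0% ± 2.21 (SD, n = 2). The ratio of 6.00 to random lists became 3.97 with GC content added to the matching, 3.12 with it in place of gene length and 3.02 without matching. All 35 are also members of other lists, so this is not a separate result.

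Regulators of the diencephalon and of the midbrain and hindbrain were also above matched genes. The 16 diencephalon and hypothalamus regulators had 10.1% against 2.47% (n = 16 genes, adjusted p = 0.0018), led by Tcf7l2 (29.2%), Barhl2 (20.99%) and Lhx1 (19.6%), with Nkx2-4 lowest at 4.79%. Their ratio to random lists was 4.10, and 1.99 with GC content added to the matching, 1.775 with it in place of gene length and 1.88 without matching. Against unmatched random lists they did not pass (n = 16 genes, adjusted p = 0.122). The 14 midbrain and hindbrain regulators had 9.50% against 3.20% (n = 14 genes, adjusted p = 0.0168), with 17.6% at Lmx1b, 14.3% at Pax2, 12.2% at Mafb and 4.55% at En1. The 12 oligodendrocyte lineage genes had 12.9% against 5.28% (n = 12 genes, adjusted p = 0.0128), with 28.9% at Olig1, 27.0% at the neighbouring Olig2, 16.5% at Mog and 0.694% at the X-linked Plp1. The 10 choroid plexus and cortical hem genes had 10.8% against 4.07% (n = 10 genes, adjusted p = 0.0344), with 16.1% at Otx2, 13.1% at Foxj1, 12.7% at Folr1 and 0.651% at Kcnj13. Of the 10, 8 lay above the median of their stratum, but Folr1 was only at percentile 42.9 of its own. The 18 pan-neuronal genes had 9.69% against 5.27% (n = 18 genes, adjusted p = 0.0449), and 14 of them lay above the median of their stratum. Rbfox3 had 34.0%, Cntn2 29.9%, Elavl3 17.5% and Nrxn1 1.10%. The 15 skeletal muscle genes had 10.5% against 4.30% (n = 15 genes, adjusted p = 0.0275), with 19.6% at Pax7, which is also expressed in the brain, 16.6% at Tnnt3, 16.0% at Des and 0.868% at Myh8. With GC content added to the matching, the ratio to random lists fell from 2.97 to 1.45 for the midbrain and hindbrain list, from 2.45 to 1.43 for the oligodendrocyte list, from 2.65 to 1.23 for the choroid plexus list and from 2.44 to 1.34 for the muscle list, and none of these passed.

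The 39 Hox genes lay below matched genes, 5.06% against 10.02% (n = 39 genes, adjusted p = 0.0449). Their windows overlap in 6 runs. With 1 gene per run the medians were 4.73% and 6.48%, and against unmatched random lists 5.06% and 5.40%, and the list did not pass in either. Hoxd8 (13.0%), Hoxd9 (11.1%) and Hoxd10 (10.8%) were highest, and Hoxb13 lowest at 0.440%. Of the receptor genes, 85.7% had no covered base in the window (n = 1464 genes, adjusted p = 0.000686). Olfr221 was highest at 18.6%, followed by Olfr90 at 13.8% and Olfr1513 at 12.2%, and Vmn2r99 was at 0%.

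The remaining lists did not pass the threshold. The astrocyte list had a median of 8.73% (n = 10 genes, adjusted p = 0.194), the endothelial and mural list 4.21% (0.752), microglia and macrophages 7.77% (0.373), meninges and mesenchyme 6.66% (0.189), erythroid and blood 6.81% (0.967), cardiac 5.54% (0.532), hepatic 3.05% (0.369), epidermal 2.23% (0.344), housekeeping 10.1% (0.124) and the non-neural transcription factors 7.17% (0.0704). Members of these lists differed widely. Lyl1, a haematopoietic transcription factor gene, had 57.3%, but its window also held a peak of 26202 bp in an intron of the neighbouring Nfix, a gene named here after its values were seen. The highest members of the other lists were Fgfr3 (33.3%), Nfe2 (32.8%), C1qb (21.9%), Actb (21.1%), Grhl3 (20.2%), Apoa2 (16.99%), Myh6 (15.1%), Pdgfrb (14.1%) and Prrx1 (13.2%). The lowest were Krt5, Hbb-bt, Lum and Cps1 at 0%, Tek at 0.623%, Gata1 at 0.973%, Trem2 at 1.005%, Hprt at 1.11%, Actn2 at 1.78% and S100b at 3.24%.

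**Figure D1:**
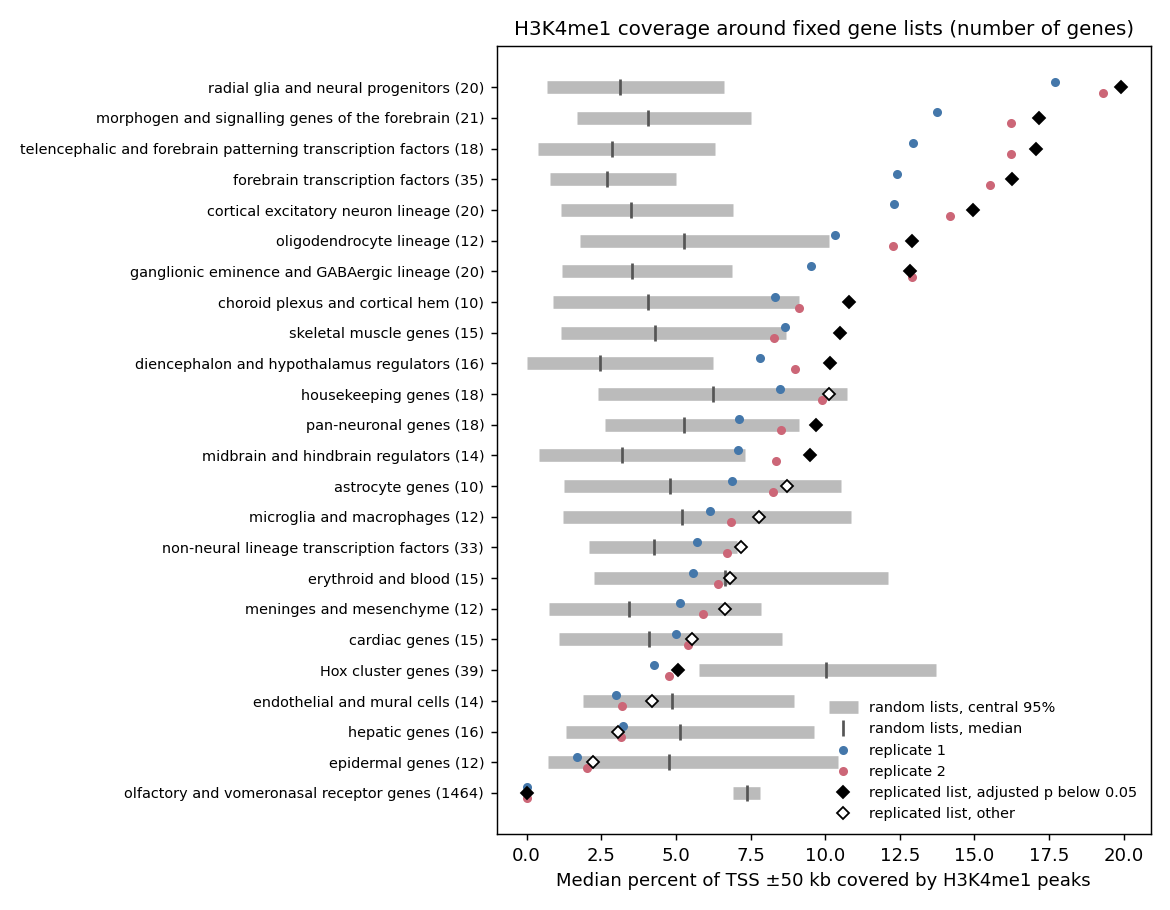
Median percent of the 50 kb on either side of the TSS covered by H3K4me1 peaks (horizontal axis) for each of 24 gene lists (vertical axis, number of genes in brackets). Diamonds are the replicated list, filled where the adjusted p was below 0.05, circles are the replicates' own lists, and grey bars are the central 95% of 10000 matched random lists with their median as a tick. Radial glia genes have the highest median, 19.9%, and receptor genes the lowest, 0%.

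In all, 12 of the 24 lists were higher and 2 lower than matched lists. The test was a two-sided percentile among 10000 random lists matched on the number of TSSs in the window and on gene length, adjusted by Benjamini-Hochberg over the lists, and the smallest p it can give is 0.0002. Genes are not independent replicates, and these p-values measure only how a list lies among other genes of the same samples. The patterning, cortical, ganglionic eminence, radial glia, signalling and forebrain transcription factor lists passed under all 13 alternative settings. Calls ended for the pan-neuronal list under 7 settings, the Hox list under 8, the choroid plexus and muscle lists under 6 each, the midbrain and oligodendrocyte lists under 4 each, the receptor list under 2 and the diencephalon list under 1. Adding GC content to the matching, chosen after the data were seen, ended those of the midbrain, oligodendrocyte, choroid plexus, muscle and receptor lists, and so did GC content in place of gene length. Some lists passed only in other settings: meninges (n = 12 genes, adjusted p = 0.0224) and housekeeping (0.0106) with windows of 10 kb, blood with 100 kb (0.0310) and non-neural transcription factors in the stronger 50% of peaks (0.0320). With GC content added the meninges list was higher (n = 12 genes, adjusted p = 0.0202) and the epidermal list lower (0.0310) than random lists. By the list of replicate 1 alone, the pan-neuronal (n = 18 genes, adjusted p = 0.103) and Hox (0.0598) lists did not pass, and by that of replicate 2 alone the pan-neuronal (0.0730), Hox (0.0624), choroid plexus (0.0628) and muscle (0.0662) lists did not.

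The second question compared developmental transcription factors of the forebrain with those of non-neural lineages, so that both sides held the same class of gene. The 35 forebrain factors had a mean of 19.5% of the window covered, against 8.33% for 33 non-neural factors, 2.34 times as much. Bcl11b, Neurod2 and Emx1 led the first list. Nfe2 (32.8%), Pax7 (19.6%) and Klf1 (18.6%) led the second, and the X-linked Gata1 was lowest there at 0.973%. The difference was 11.2 percentage points (95% bootstrap interval over genes 6.96 to 15.5), with p = 2e-05 in a two-sided permutation test of 100000 resamples. Each replicate showed it, at 9.17 ± 1.37 points (SD, n = 2). Its size depended on the window, at 30.1 points with windows of 10 kb and 5.43 with 100 kb. The lists share 0 members, and GC content of the windows was not controlled in this contrast.

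Over the whole genome, the gene with the most of its window covered was Pipox (70.1%), whose window also holds the TSS of Sez6. It was followed by Tcf20 (67.2%), Flrt1 (66.7%), G430095P16Rik (64.2%), the corepressor gene Ncor2 (60.8%), Ccdc85c (55.3%), Foxo6 (52.9%), Stra6 (52.9%), the reelin receptor gene Lrp8 (51.7%) and Celsr1 (51.6%). The windows of Tcf20, Flrt1, G430095P16Rik, Ccdc85c and Celsr1 also hold TSSs of other genes. That of G430095P16Rik includes the peak of 26202 bp in an intron of Nfix. Over all 21728 protein-coding genes the median was 5.38%, and 17.0% of genes had no covered base in the window.

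The peak with the highest fold enrichment lay in an intron of Thra, the thyroid hormone receptor alpha gene (chromosome 11, 98747779 to 98753512), at 12.5, with 12.1 ± 1.91 for the matching peaks of the replicates (SD, n = 2). The next were in introns of Zmiz1 (chromosome 14, 25583725 to 25590935, fold 12.2), Nol4l (chromosome 2, 153481315 to 153485808, 12.1), Hdac5 (chromosome 11, 102214375 to 102220963, 12.1) and Ncor2 (chromosome 5, 125146962 to 125161299, 11.9). The region between Dlx1 and Dlx2, which is known to hold forebrain enhancers (chromosome 2, 71533982 to 71543407), had 3 peaks over 49.4% of its length. The strongest of them, 2820 bp from 71539171 to 71541990, had a fold of 5.67. The region between Dlx5 and Dlx6 (chromosome 6, 6868569 to 6877804) had 2 peaks over 14.6% of its length, of folds 2.49 (6873991 to 6874786) and 2.87 (6875161 to 6875709). In the replicates' own lists 44.0% ± 2.07 and 10.9% ± 0.605 of these regions were covered (SD, n = 2). All 5 peaks have their midpoint between genes.

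**Figure D2:**
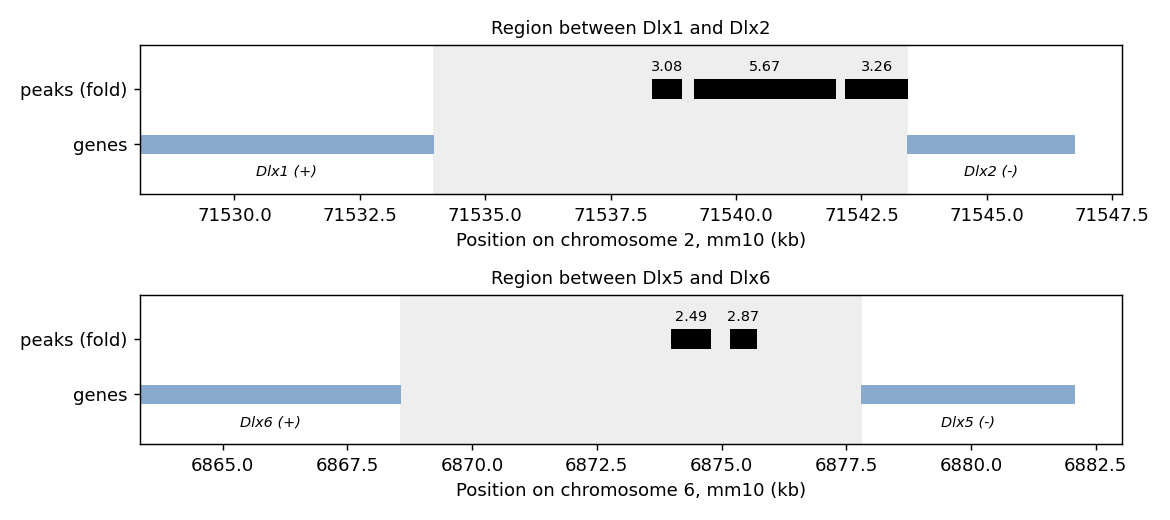
Maps of the regions between Dlx1 and Dlx2 (top) and between Dlx5 and Dlx6 (bottom), with position in kb on mm10 on the horizontal axis. Blue bars are genes with their strand, black bars are replicated peaks with their fold enrichment, and shading marks the region, which holds 3 peaks at the top and 2 at the bottom.

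The third question was whether the mark lay on or beside start sites. At CpG-rich TSSs, the class of most broadly expressed and developmental genes, it lay beside them. Over 10059 such TSSs, a mean of 14.2% of the bases within 100 bp of the start was covered. From 1 to 2 kb away the mean was 24.02% of bases upstream and 61.8% downstream. Coverage per 100 bp bin was highest, 70.0%, at 1150 bp downstream. The flanks had 3.02 times the coverage of the centre, and 3.28 ± 0.129 times in the replicates (SD, n = 2). At 8611 CpG-poor TSSs the order was the opposite, 11.3% at the centre and 5.35% in the flanks, a ratio of 0.472 (replicates 0.462 ± 0.0155, SD, n = 2). The 3058 TSSs between these classes had 41.8% at the centre and a ratio of 0.540. Their coverage per bin was nevertheless highest, 50.9%, at 550 bp downstream, which lies outside the centre and the flanks. At CpG-poor TSSs it was highest, 11.6%, at 50 bp downstream. The gap between CpG-rich and CpG-poor ratios was larger than the spread between replicates.

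**Figure D3:**
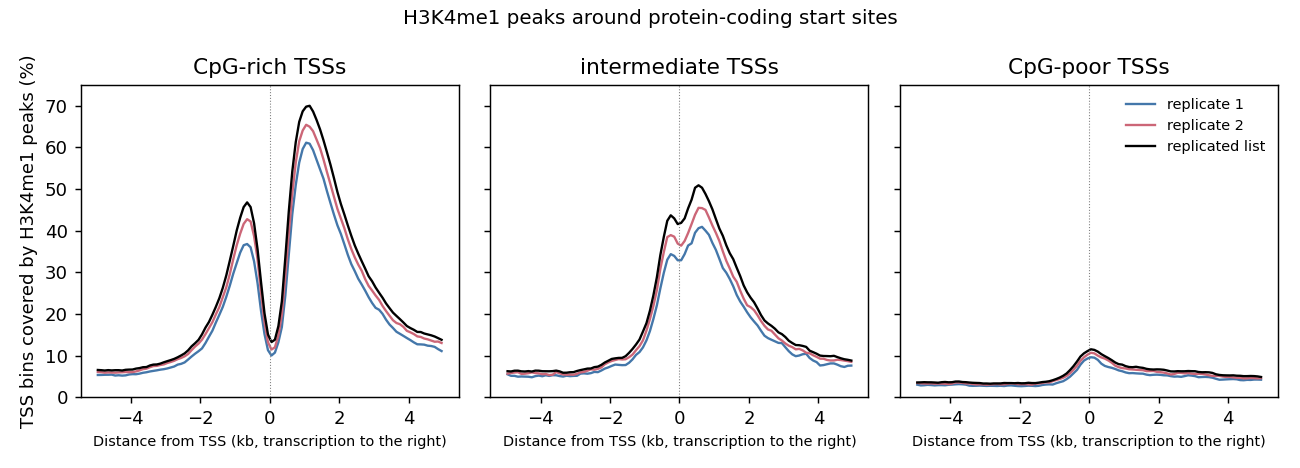
Mean percent of bases covered by H3K4me1 peaks in 100 bp bins (vertical axis) by distance from the TSS in kb (horizontal axis). Transcription runs to the right, and panels are CpG-rich, intermediate and CpG-poor TSSs. Lines are replicate 1, replicate 2 and the replicated list. Coverage at CpG-rich TSSs dips to 14.2% at the centre between flanks of 24.02% and 61.8%, and CpG-poor TSSs have no such dip.

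Most peaks lay away from promoters. Of the replicated peaks, 9.04% had their midpoint within 1 kb of a protein-coding TSS, 57.9% lay elsewhere inside a protein-coding gene (54.2% in introns) and 33.1% between genes. Peaks shifted at random along their chromosomes gave 1.62%, 39.6% and 58.8%, so promoters held 5.59 times and intergenic sequence 0.563 times the shifted share. In all, 44.0% of peaks were more than 50 kb from any such TSS. The promoter share of the replicates was 7.77% ± 0.128 (SD, n = 2). It moved with its definition, to 3.85% within 500 bp, 17.5% within 2.5 kb and 14.1% when any base of the peak counted.

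Promoter peaks had a median fold enrichment of 3.55, genic peaks 3.21 and intergenic peaks 3.12. In the replicates these were 3.40 ± 0.149, 3.02 ± 0.0136 and 2.98 ± 0.0394 (SD, n = 2), so the promoter class stood apart by more than the spread. Peaks over 2 kb wide were most frequent inside genes, 10.4% against 6.62% between genes and 4.19% at promoters. A promoter peak of that width must span the TSS, since its midpoint lies within 1 kb of it. Wide peaks beside a TSS can thus count in the other classes, and the low promoter share may partly reflect this definition. No test across peaks was made, since peaks are not independent replicates.

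The replicates shared most of their strong peaks. A peak counted as shared when the overlap made up at least 50% of either peak. By that rule 70.8% of replicate 1 peaks and 62.9% of replicate 2 peaks were shared, against 5.97% and 5.62% after random shifts, and the Jaccard index of covered bases was 0.557 against 0.0228. Among peaks ranked by fold enrichment in 4 equal parts, 97.5% and 96.6% were shared in the strongest part, and 47.0% and 34.96% in the weakest. When the overlap had to reach 50% of both peaks, 45.0% and 43.8% were shared. Across 112783 best-matching peak pairs, which are not independent replicates, log2 fold enrichment had a Pearson r of 0.650 and a Spearman rho of 0.599. Of these pairs, 88.4% agreed within 1.5 times, but the share among peaks paired at random was not computed. Only 2 peaks had identical ends in both lists.

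The authors' replicated list held 60.9% of the pooled peaks, each with the same coordinates and values. All 110963 pooled peaks that met a peak of each replicate by the 50% rule were in it, as were 17525 that did not. The 82596 pooled peaks left out were weaker, with a median fold of 2.23 against 3.20, and narrower, 248 bp against 698 bp.

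The last question was whether the dissections differed around markers of particular regions or cell types. Around forebrain genes, replicate 1 covered less than replicate 2. The values are list medians of each gene's coverage in replicate 1 minus that in replicate 2. They were -3.88 percentage points for the patterning transcription factors, -2.59 for the cortical list, -2.37 for radial glia, -1.89 for signalling genes, -1.85 for the ganglionic eminence list, -1.52 for both the diencephalon and oligodendrocyte lists and -2.65 for forebrain transcription factors. These 8 lists were lower than matched random lists, whose medians lay between -0.524 and -0.206 (list sizes from n = 12 to n = 35 genes, adjusted p from 0.0006 to 0.0326). The median of the Hox genes, 0.0380 points, was above that of their random lists, -0.674 (n = 39 genes, adjusted p = 0.0006). Receptor genes also passed, but 82.9% of them had no covered base in either replicate, which fixes their median at 0, so that call carries no information.

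No other list passed. These were the pan-neuronal, midbrain and hindbrain, astrocyte, choroid plexus, microglia, housekeeping, endothelial, meningeal, blood, cardiac, hepatic, muscle, epidermal and non-neural transcription factor lists (list sizes from n = 10 to n = 33 genes, adjusted p from 0.156 to 0.863). As a log2 ratio of the replicates, chosen after the data were seen, the patterning and forebrain transcription factor lists passed, with medians of -0.32 and -0.28 (n = 18 and n = 35 genes, adjusted p = 0.0084 each). The cortical (-0.26), ganglionic eminence (-0.26), diencephalon (-0.25), oligodendrocyte (-0.22), radial glia (-0.19) and signalling (-0.19) lists were also below their random lists but did not pass, and lists were not tested against each other. The Hox list, at 0.01 against -0.10, passed as higher (n = 39 genes, adjusted p = 0.0024). With random lists matched on the mean coverage of both replicates in place of TSS number and gene length, also chosen after the data were seen, 4 lists passed. They were the patterning, cortical, forebrain transcription factor and Hox lists. The Hox call ended with −log10 q of at least 2, in the stronger 50% of peaks, where the list lay below its random lists, and with windows of 10 and 100 kb. It also ended with 1 gene for each of the 6 runs of overlapping windows, so the p over 39 genes overstates its support. The oligodendrocyte call also ended in the stronger 50% of peaks, with both other windows and with 1 gene per run. This compares 2 libraries and has no replicate check.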

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

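Both matchings with GC content, matching on mean coverage, 1 gene per run of overlapping windows, autosomal genes alone and the log2 ratio were chosen after seeing the data. The difference between forebrain and non-neural transcription factors kept its direction and passed under the 11 alternatives run on it. The highest permutation p was 0.00419. Neither setting with GC content was run on this contrast, so GC content was not controlled in it. The difference was 7.85 peaks by number of peaks. In the other 10 it lay between 5.43 percentage points, with windows of 100 kb, and 30.1, with windows of 10 kb. Where values moved, the cause was not tested unless the setting itself shows it. Unknown depth limits all coverage values, and 1 SD from 2 replicates is a narrow measure of spread.

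The share of replicate 1 peaks that were shared became 77.0% with 1 bp of overlap and 45.0% with 50% of both peaks. For replicate 2 it became 68.7%, 43.8%, and 69.7% after merging within 1 kb. The Jaccard index was 0.564 with −log10 q of at least 2, 0.577 in the stronger 50% of peaks, 0.559 with equal numbers of peaks and 0.623 after merging. Pearson's r was 0.656 with 1 bp, 0.685 with 50% of both, 0.654 with −log10 q of at least 2 and 0.617 in the stronger 50%, and Spearman's rho 0.653, 0.590 and 0.549 in the last 3. The stronger 50% of replicated peaks is 64244 by construction.

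The promoter share was 3.85% within 500 bp, 17.5% within 2.5 kb, 14.1% by any base, 12.6% with the TSSs of every transcript, 11.6% in the stronger 50%, 6.84% in the pooled list and 7.68% to 7.86% with a replicate left out. The flank to centre ratio at CpG-rich TSSs was 3.54 in the stronger 50%, 3.44 over every transcript and 3.19 to 3.38 with a replicate left out. At CpG-poor TSSs it was 0.516, 0.564 and 0.451 to 0.473. The ratio of promoter to intergenic fold was 1.14, and 1.22 within 2.5 kb, 1.03 in the stronger 50% and 1.25 in the pooled list.

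Without matching, 6 lists were higher in place of 12. In place of 2 lower lists there was 1 with windows of 10 kb, with windows of 100 kb, by number of peaks, in the pooled list, without matching, with 1 gene per run of overlapping windows and with either replicate left out (1 to 1). Of the 12 higher lists 8 passed with GC content added to TSS number and gene length, and 8 with it in place of gene length. Either ended the calls of the midbrain and hindbrain, oligodendrocyte, choroid plexus and muscle lists, because random lists rose, and that of receptor genes, since both medians were 0. Matching none of these features also ended the first 4.

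Replicate differences passed for 4 lists by log2 ratio and for 4 matched on mean coverage, in place of 10. Without the receptor list, whose call carries no information, these were 3, 4 and 9. For coverage at single lists, 266 calls were the same, 38 were lost and 8 gained, with no change of direction in a list that passed. For the replicate difference at single lists, receptors left out, 161 were the same, 19 lost and 3 gained: midbrain and hindbrain with windows of 10 kb and in the stronger 50% of peaks, and housekeeping with 10 kb. The Hox difference became -0.874 points in the stronger 50%, below its random lists, and lost its call. Coverage at 98 named genes stayed within the spread 208 times and moved 282 times, and 111 of the 490 values were above the main one.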

Other observations

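The gene lists of the first paragraph, the comparison of X and autosomes in the pooled list, and the matching on GC content and mean coverage were chosen only after results were seen.

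Chromatin regulators of neural development and immediate early genes were among further groups with high H3K4me1 coverage. The 20 chromatin regulators had a median of 13.3% of the 50 kb on either side of the TSS covered, 2.21 times random lists (n = 20 genes, adjusted p = 0.0072 by Benjamini-Hochberg over 6 lists), led by Tet3 (45.3%), Auts2 (34.97%) and Arid1b (30.02%). The X-linked Mecp2 had 0%. The 14 immediate early genes had 12.7%, 3.05 times random lists (n = 14 genes, adjusted p = 0.0144), with 29.0% at Ier2, 27.9% at Junb and 22.5% at Fosb. With GC content added to the matching, the adjusted p was 0.0030 for the n = 20 chromatin regulator genes and 0.684 for immediate early genes. Cell cycle genes had 9.37% (n = 20 genes, adjusted p = 0.0504), axon guidance genes 7.85% (0.0894), mature synapse genes 7.07% (0.624) and neuropeptide genes 4.04% (0.426), and did not pass. Axon guidance genes spanned a wide range, from 43.5% at Epha4 and 38.3% at Efnb2 to 0.583% at Robo1, and passed with GC content added (n = 21 genes, adjusted p = 0.0024).

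The widest replicated peaks, chosen after their values were seen, lay in introns of Gse1 (chromosome 8, 120502354 to 120529609, 27256 bp), Nfix (26202 bp), Lrp8 (26154 bp), Foxn3 (25479 bp) and Notch1 (20429 bp), with folds of 10.1, 9.04, 10.4, 8.32 and 10.99.

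The X chromosome had 10.6 and 13.8 peaks per Mb in replicates 1 and 2, against 76.8 and 78.8 on autosomes. In the pooled list, made from both samples, the X had 15.0 peaks per Mb and 0.173 times the autosomal density. The ratio was 0.138 and 0.174 in replicates 1 and 2. Pooling raised the autosomal density only to 87.1 peaks per Mb, so it cannot show whether fewer reads from the X lowered its density. X genes had 0.229 times the coverage of autosomal genes in the same strata of gene density, gene length and repeats (95% bootstrap interval over genes 0.204 to 0.258). Without matching the ratio was 0.155, so these features accounted for at most a part of the low X coverage, and most of it remained. Fewer reads from the X, mappability and filters of the alignments, and a true difference of the mark stay open. Each replicate pooled male and female embryos, so the mark could not be compared by sex.

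Replicate 1 covered less than replicate 2 around forebrain genes. A lower yield of replicate 1 that costs most where coverage is high may account for part of it. With random lists matched on mean coverage 4 lists still passed, 3 of them lower and the Hox list higher. Bounds chosen before this test were 2 or fewer for a yield effect and 5 or more against it. The count lay between them and the lists share members, so it cannot decide. A different share of telencephalon and diencephalon in the dissections was neither shown nor excluded, since the mean log2 ratio of replicate 1 to replicate 2 differed by -0.0384 between these lists (95% bootstrap interval -0.161 to 0.0839, permutation p = 0.551). The extra input file of replicate 1 was not tested.

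Coverage around skeletal muscle genes, 10.5% against 4.30% in random lists (95% of them between 1.15% and 8.68%), stood out in a tissue without skeletal muscle. Peaks of neighbouring genes are a candidate explanation, since within 10 kb of the TSS the list had 10.1% against 8.10% (0% to 16.3%, n = 15 genes, adjusted p = 0.678). GC content of the windows is another, since with GC added to the matching on TSS number and gene length random lists rose to 7.82% (4.10% to 12.7%) and the call ended (n = 15 genes, adjusted p = 0.305). With GC in place of gene length they had 8.60% (4.89% to 13.5%, n = 15 genes, adjusted p = 0.552). The design gives no biological explanation to test.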
